A study of Mus musculus with 16 samples.

How the data were processed

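RNA was measured by sequencing in haematopoietic stem cells (HSCs) of Mus musculus in 16 libraries. Per the labels, cells came from leg and hip bones, were enriched for c-kit with magnetic beads and sorted by flow cytometry, and 1 extraction and library protocol is given for all samples. The 4 groups were wild type (WT) naive, WT infected with Mycobacterium avium for 1 month, Batf2 knockout (KO) naive and Batf2 KO infected, with 4 libraries each. The labels number the libraries of a group from 1 to 4 and do not say whether they are separate animals, so p-values measure the spread between these samples, which may be technical.

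The deposited gene table is a normalized signal, not raw counts. Its values are gene counts that the authors divided by DESeq2-type factors varying by gene and library. The median-of-ratios size factor computed from them was 1.02 in all 16 libraries. Low values were whole multiples of the commonest repeated value, within a tolerance of 0.1, in 15.4% to 47.5% of cases per library, so whole reads could not be recovered. The authors' processing notes name STAR, DESeq2 and the mm10 build without versions, and the counting strand is not stated. Per the file headers, the authors' 2 deposited DESeq2 tables hold log2 fold changes with standard errors, a Wald score, and p-values with adjusted p-values for infection in WT and in KO. Also per the file headers, the authors' enrichment tables hold gene set scores (CERNO statistic, area under the curve and effect size) with p-values, and 3 of the gene ontology tables hold a header line only. The DESeq2 tables do not rest on the values of the gene table: both print 1 mean level per gene, which differed more than 8-fold from the general offset to the gene table in 180 of 9701 genes with a mean above 100 in WT. The comparison of these tables, and the share of 50-base transcript windows found in other genes (GENCODE M21 transcripts, either strand), were chosen after the values were seen.

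Column totals were 15082600 to 22019300 normalized counts, and 12911 to 14978 genes were above 0. Where at least 8 genes shared the commonest repeated low value, that value was taken as 1 read of those genes. In these 14 libraries 5 to 51 genes lay at 2 to 5 times that value to within 0.002%, and 0 to 2 midway between whole steps (1.5 to 4.5 times), a check added after the values were seen; in 2 libraries up to 5 genes lay at 0.5 of the value. As other genes have other factors, dividing the column total by it gives only an estimate, 5940000 to 17700000 reads. No estimate was made in WT naive library 2 or KO naive library 2. No counting interval or limit for a value of 0 was computed, because the values are not counts. Of 24972 table entries, 26 are named as dates (gene symbols altered by a spreadsheet, 0.112% to 0.215% of a library's total) and were left out; 7397 genes were at 0 in all libraries.

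Values were analysed as log2(value + 1), with a pseudocount of 1. Genes with a value of at least 10 in at least 4 libraries were tested, 13384 in all. The design had assumed raw counts; edgeR, which it named, was not used, because the values are normalized. The test was limma 3.58.1 in R 4.3.3, with a trend in the prior variance, 1 mean per group over all 16 libraries, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The groups, the comparisons, the 26 gene lists, the naming rule and most of the alternatives were fixed before the data were examined. The 5 comparisons were infection in WT, infection in KO, KO against WT in naive cells, KO against WT in infected cells, and the difference between the infection responses. Genes named are Batf2, the 5 largest called increases and decreases with non-overlapping groups, the 5 smallest p-values, 2 called members per list, every called gene where 10 or fewer were called, and the 2 most highly expressed members of a list as examples of genes not called; not every gene the rule takes is printed. Predicted genes are skipped among the largest changes and the smallest p-values.

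Each list was tested with limma camera at a preset correlation between genes of 0.01 and again with the correlation estimated, adjusted over the 26 lists. Member counts were adjusted over all genes and over the list alone. Batf2 was also compared by an exact two-sided permutation test. The overall size of the infection response was compared between genotypes by permuting genotype labels within naive and within infected libraries (4900 relabellings).

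Deviations from the group mean correlated between libraries with the same number in different groups at 0.630 to 0.880 in all 24 pairs, against 0.458 to 0.735 for the other number of the same set (1 with 2, 3 with 4) and -0.788 to -0.574 across the sets. The rule for pairing, a correlation over 0.1 in every same-numbered pair, was met, and the numbers were therefore read as pairing the samples. The ranges overlap, however, and only 10 of 16 libraries correlated best with their own number in every other group, so part of this is the difference between the sets. With the set in place of the number as a block, a fit added later, 229 genes passed in WT and 143 in KO. A fit with replicate number as a block is given beside the unblocked fit for the number of genes called in each comparison, and elsewhere where stated. Fits of libraries 1 and 2 only and of libraries 3 and 4 only are given too. Counts of list members are without the block unless it is named, and many were higher with it. Class I genes at an unadjusted p under 0.05 in limma, for infection in WT, went from 6 to 19. Other alternatives were another filter or none, another pseudocount, equal column totals, quantile normalization, the first principal component of the residuals as a covariate, only the compared groups, a fold minimum, and each library left out in turn. Fits leaving out 1 library had no block, so they also unbalanced libraries 1 and 2 against libraries 3 and 4 in that group. The fit was checked on simulated data, drawn from the gene means, replicate-number effects and residual spread of these libraries, with genes shifted by known folds. Genes were drawn independently and the number effect was the same in every group, so the model with the block held by construction. Gene positions are from GENCODE M21 (mm10, counted from 1).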

Results

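Transcript levels were measured by bulk RNA sequencing of sorted HSCs from WT and Batf2 KO mice, naive or infected for 1 month with M. avium, a slow-growing mycobacterium that sustains interferon-gamma production. Each of the 4 groups held 4 libraries. Column totals ranged from 15082600 to 22019300 normalized counts, and the reads estimated from repeated low values from 5940000 to 17700000 in the 14 libraries where this could be done. Values are normalized counts given as mean ± SD, and changes are log2 differences with the standard error (SE) of the limma fit over 13384 tested genes. The first principal component held 61.7% of the variance and separated all libraries numbered 1 and 2 from all libraries numbered 3 and 4, in every group alike. The second component held 9.33%. The highest correlation between any pair of libraries was 0.977, and 0 pairs of columns were identical.

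**Figure D1:**
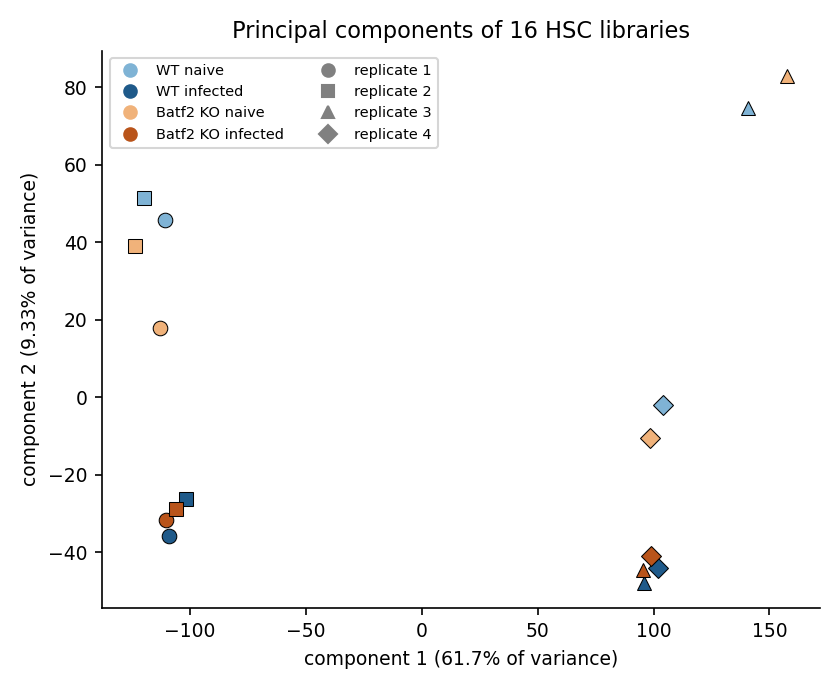
Position of the 16 HSC libraries on the first 2 principal components of log2(normalized value + 1), colour giving the group and shape the replicate number. Component 1 (61.7% of variance) separates libraries 1 and 2 from libraries 3 and 4, and component 2 holds 9.33%.

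Batf2 (ENSMUSG00000039699, chromosome 19, 6140983 to 6172476, plus strand), a basic leucine zipper transcription factor induced by interferon, was listed at 0 in all 8 KO libraries. In WT it was 48.8 ± 39.6 in naive cells (n = 4) and 1308 ± 1681 in infected cells (n = 4). The 4 naive values were 27.1, 3.85, 81.0 and 83.0, and the 4 infected values were 456, 343, 3823 and 608. The increase in WT was 4.64 (SE 0.904), with an adjusted p of 0.0385 in limma and 0.0037 with the replicate block. Every infected library was above every naive library, and the exact permutation p was 0.0286, the smallest that 70 relabellings can give. The adjusted p stayed under 0.05 in 2 of the 8 fits that left out 1 library and reached 0.163. It was 0.117 in libraries 1 and 2 only and 0.430 in libraries 3 and 4 only.

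**Figure D2:**
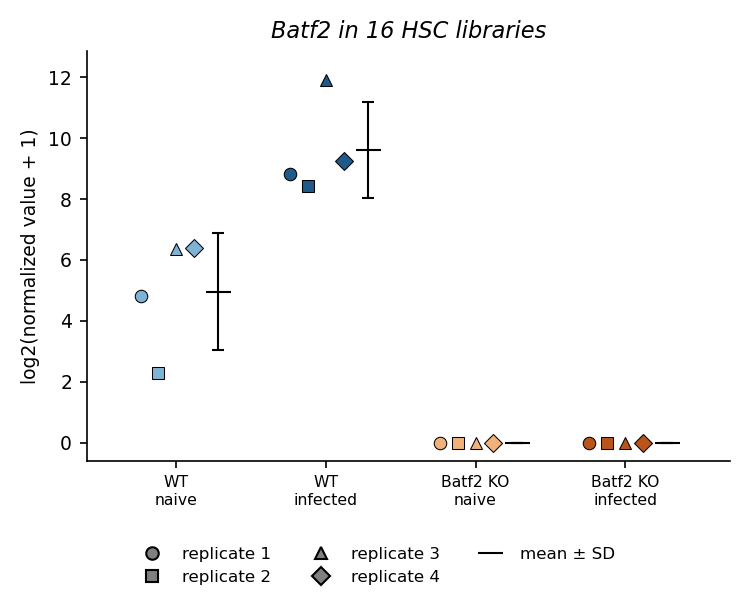
Batf2 level, as log2(normalized value + 1), in each of the 16 libraries by group, with the group mean ± SD. All 8 KO libraries sit at 0, and the 4 infected WT libraries (343 to 3823 normalized counts) lie above the 4 naive WT libraries (3.85 to 83.0).

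The first comparison asked which transcripts changed in WT HSCs after infection. The interferon-gamma GTPases, which attack the vacuoles of intracellular pathogens, rose most: 13 of 21 tested members rose, none fell, and the list's median change was 3.72. Iigp1 went from 457 ± 97.3 to 19400 ± 17720 (n = 4 each, change 5.07, SE 0.475, limma adjusted p 0.000338). H2-Eb1, a class II antigen-presenting chain, went from 345 ± 236 to 9322 ± 4391 (n = 4 each, change 4.89, SE 0.772). The macrophage genes Mrc1, Siglec1 and Slc40a1 fell. In all, 46 genes passed the threshold, 43 higher and 3 lower, and with the replicate block 316 did, 252 higher and 64 lower, including all 46.

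Among the largest increases in WT was Cxcl9, a chemokine that draws in activated T cells, which went from 3.68 ± 4.85 to 4016 ± 6211 (change 9.28, SE 1.20, limma adjusted p 0.00154). Apol10b, Apol9a and Apol9b, of the apolipoprotein L family, and Gbp10, a guanylate-binding protein, rose by 9.08 (SE 0.961), 7.30 (SE 1.10), 7.11 (SE 1.20) and 7.34 (SE 0.983). Naive means were 5.14 or less for the first 4 of these, and naive values of Gbp10 ranged from 0.926 to 104, so these log2(value + 1) differences depend on the pseudocount; all 5 genes passed with a pseudocount of 10 as well. Other genes with small p-values were Irgm2 (3.52, SE 0.369), a GTPase, and Zbp1 (4.08, SE 0.434), a sensor of Z-form nucleic acid, both with a limma adjusted p of 0.000345. Each called gene named here was higher, or lower, in infected than in naive cells in 4 of 4 same-numbered pairs. Iigp1 lies on chromosome 18 (60376027 to 60392634, plus strand), Cxcl9 on chromosome 5 (92321347 to 92328079, minus strand) and Apol10b on chromosome 15 (77583819 to 77596125, minus strand).

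Lists of immune genes rose in WT in the camera test of limma, both at the preset correlation and with an estimated correlation. For the interferon-gamma GTPases the adjusted p was 5.68e-78 and 0.000128 with an estimated correlation, and 19 of 21 members passed adjusted over the list alone. Of 39 antiviral interferon-stimulated genes, 4 rose without the block, among them Zbp1 and Oasl2 (2.09, SE 0.283), and 24 passed adjusted over the list alone. With the block 38 had an unadjusted p under 0.05, against 24 without it. The list's median was 1.79 (camera adjusted p 4.26e-46, and 0.000128 with an estimated correlation). Of 21 interferon signalling genes, 9 passed adjusted over the list alone (median 0.94, adjusted p 1.58e-16, and 0.00437 with an estimated correlation). Irf8, a transcription factor of myeloid cells and an example of a member that did not pass, changed by 2.08 (limma adjusted p 0.438, and 0.00577 with the block). For class I antigen presentation 0 of 20 members passed in limma over all genes (6 at an unadjusted p under 0.05) and 2 adjusted over the list alone, but all 20 changes were positive and the list rose (median 1.033, adjusted p 4.90e-12, and 0.0164 with an estimated correlation). With the block 17 of these 20 rose, and H2-D1 and B2m, its most abundant members, changed by 0.60 and 0.77. Class II genes, which present peptides to helper T cells, had a median of 3.13 (adjusted p 1.63e-18, and 0.0140 with an estimated correlation).

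Of 12 class II genes, 3 rose in WT without the block and 6 passed adjusted over the list alone. Ciita, the master regulator of the class, rose by 4.85 (SE 0.713) beside H2-Eb1. Of 18 chemokine, cytokine and checkpoint genes 2 rose without the block and 10 passed adjusted over the list alone. With the block 14 had an unadjusted p under 0.05, against 10 without it. The list's median was 2.77, and 2.78 without Nos2, listed at 0 in a whole group (camera adjusted p 1.91e-24, and 0.00437 with an estimated correlation). The 2 that rose were Cxcl9 and Cxcl11 (6.71, SE 1.33, limma adjusted p 0.0435), the latter annotated as a polymorphic pseudogene. NF-kB and TNF targets rose as a list (median 1.66, adjusted p 7.42e-11, and 0.0385 with an estimated correlation), a call lost at adjusted p = 0.193 with the block and an estimated correlation. Of its 21 members 0 passed in limma without the block, over all genes or adjusted over the list alone, and 9 had an unadjusted p under 0.05, against 13 with the block. Their median was 3.60 in the libraries numbered 3 and 0.47 to 1.02 in the other numbers. Of 20 interferon-linked cell death genes 3 rose, Apol9a, Apol9b and Casp12, a caspase (1.83, SE 0.304), and 4 passed adjusted over the list alone. That list's median was 0.60 (adjusted p 4.51e-08, and 0.00996 with an estimated correlation). Lymphoid priming genes rose as a list (median 0.62, adjusted p 0.000136, and 0.0140 with an estimated correlation), a call lost at adjusted p = 0.0517 with the block and an estimated correlation. Of its 20 members 0 passed in limma without the block, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05, against 7 with the block.

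Markers of other cells moved with infection in WT. Of 20 macrophage and monocyte markers 3 fell without the block and 10 passed adjusted over the list alone (median -2.28, camera adjusted p 2.72e-20, and 0.00554 with an estimated correlation). At an unadjusted p under 0.05 in limma there were 12 of these markers, and 13 with the block. Mrc1, the mannose receptor, fell by 4.28 (SE 0.757), from 469 ± 539 to 15.2 ± 7.31, Siglec1, a sialic acid receptor, fell by 5.12 (SE 0.970), and Slc40a1, the iron exporter, fell by 2.77 (SE 0.513). Their limma adjusted p-values were 0.0167, 0.0309 and 0.0251. Dendritic cell markers rose as a list (9 tested, median 0.97, adjusted p 8.40e-05, and 0.0115 with an estimated correlation), and 2 passed adjusted over the list alone. As written, that list shares Bst2 with the antiviral list, and Irf8 and Batf3 with the interferon signalling list. It shares Flt3 and Ccr9 with lymphoid priming, so its rise is not separate from theirs and does not by itself show dendritic cells. Erythroid markers had a median of -1.15 (15 tested, adjusted p 8.40e-05), a call lost at adjusted p = 0.167 with an estimated correlation. T and NK markers had a median of 1.44 (10 tested, adjusted p 0.0172), lost at adjusted p = 0.0530 with an estimated correlation and at 0.0566 with the block. Neutrophil (16 tested, median -0.32, adjusted p 0.185), B and plasma cell (13 tested, 0.10, 0.983), basophil and mast cell (8 tested, 0.34, 0.556) and stromal and endothelial markers (13 tested, 0.27, 0.556) did not pass. In these 6 lists and among dendritic markers 0 members passed over all genes in limma without the block, and 1 stromal marker passed adjusted over the list alone. At an unadjusted p under 0.05 there were 4 dendritic, 2 erythroid, 2 stromal and 0 other members. With the block there were 5 dendritic, 8 erythroid, 2 stromal, 2 T and NK and 1 neutrophil marker. Levels of some markers were high and uneven: S100a9, of neutrophils, was 6344 to 106900 in naive and 6448 to 32530 in infected WT libraries. Its highest values were in naive library 4 (106900 in WT, 85960 in KO). Cd79a, of B cells, was lower, at 20.1 to 689 in naive and 21.2 to 320 in infected WT libraries. Whether other cells were in the sorted samples was not tested.

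Among stem cell, lineage, cycle and housekeeping lists in WT, the HSC self-renewal list did not pass (37 tested, median 0.25, adjusted p 0.106), and 0 of its genes passed over all genes or adjusted over the list alone. Of 33 myeloid commitment genes 1 rose, Csf2rb, the shared beta chain of the GM-CSF receptor (3.14, SE 0.520), while the list did not pass (median 0.03, adjusted p 0.748). Megakaryocyte and erythroid priming genes had a median of -0.31 (29 tested, adjusted p 0.0600, 0.000300 with the block, and 0.0291 with the block and an estimated correlation). The p53 targets did not pass (24 tested, median 0.31, adjusted p 0.377). Medians were -0.17 for S phase genes (30 tested, adjusted p 0.00169), -0.23 for G2 and mitosis genes (30 tested, 0.00417), -0.43 for ribosomal proteins (43 tested, 9.82e-10), -0.36 for oxidative phosphorylation (50 tested, 7.33e-05) and 0.99 for immediate-early genes (25 tested, 1.20e-05). All 5 calls were lost with an estimated correlation: adjusted p = 0.238, 0.167, 0.238, 0.573 and 0.238 with an estimated correlation. The ribosomal, oxidative phosphorylation and immediate-early shifts lay mostly in the pair numbered 3 (-1.23, -1.03 and 2.89). With 1 WT library left out, the list calls in WT held in all 8 fits, except those of S phase genes (6 of 8), G2 and mitosis genes (7), immediate-early genes (7), oxidative phosphorylation (6) and T and NK markers (6). Without WT naive library 3 the immediate-early median was 0.06 (adjusted p 0.652) and the oxidative phosphorylation median 0.12 (adjusted p 0.905). In these lists 0 members other than Csf2rb passed over all genes in limma without the block, and 0 other members adjusted over the list alone. At an unadjusted p under 0.05 there were 2 HSC, 1 megakaryocyte or erythroid, and 0 other genes besides Csf2rb. With the block there were 12 HSC, 14 megakaryocyte or erythroid, 6 myeloid, 11 ribosomal, 12 oxidative phosphorylation and 6 immediate-early genes, and 5 or fewer in each other list.

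The count of 46 was 32 without WT infected library 3, 18 with only the WT groups in the fit, 86 in libraries 1 and 2 only, and 0 in libraries 3 and 4 only. There limma gave 700 genes at an unadjusted p under 0.05 without the block, close to the 669 given by chance, and 1059 with it. The median log2 level of the GTPase list was 7.93 and 8.06 in WT naive libraries 3 and 4. It was 14.1 and 11.8 in the infected ones. Over all libraries 513 genes had an unadjusted p under 0.05, and 2086 with the block. Non-overlapping naive and infected values were seen in 404 genes (3.02% of those tested). Chance would give 2.86% if the libraries were exchangeable, which the difference between the sets prevents. The same count for KO against WT was 35 genes (0.262%) in naive and 48 (0.359%) in infected cells. Equal column totals moved the median of all genes to 0.0991. Of the fits leaving out 1 WT library, the call held in 2 of 8 for Siglec1 and Slc40a1, in 4 for Mrc1, in 1 for Cxcl11, in 5 for Apol9b, and in 7 for Casp12 and Csf2rb. It held in all 8 for Iigp1, Irgm2, Zbp1, Cxcl9, Apol10b, Apol9a, Gbp10, Ciita, H2-Eb1 and Oasl2.

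**Figure D3:**
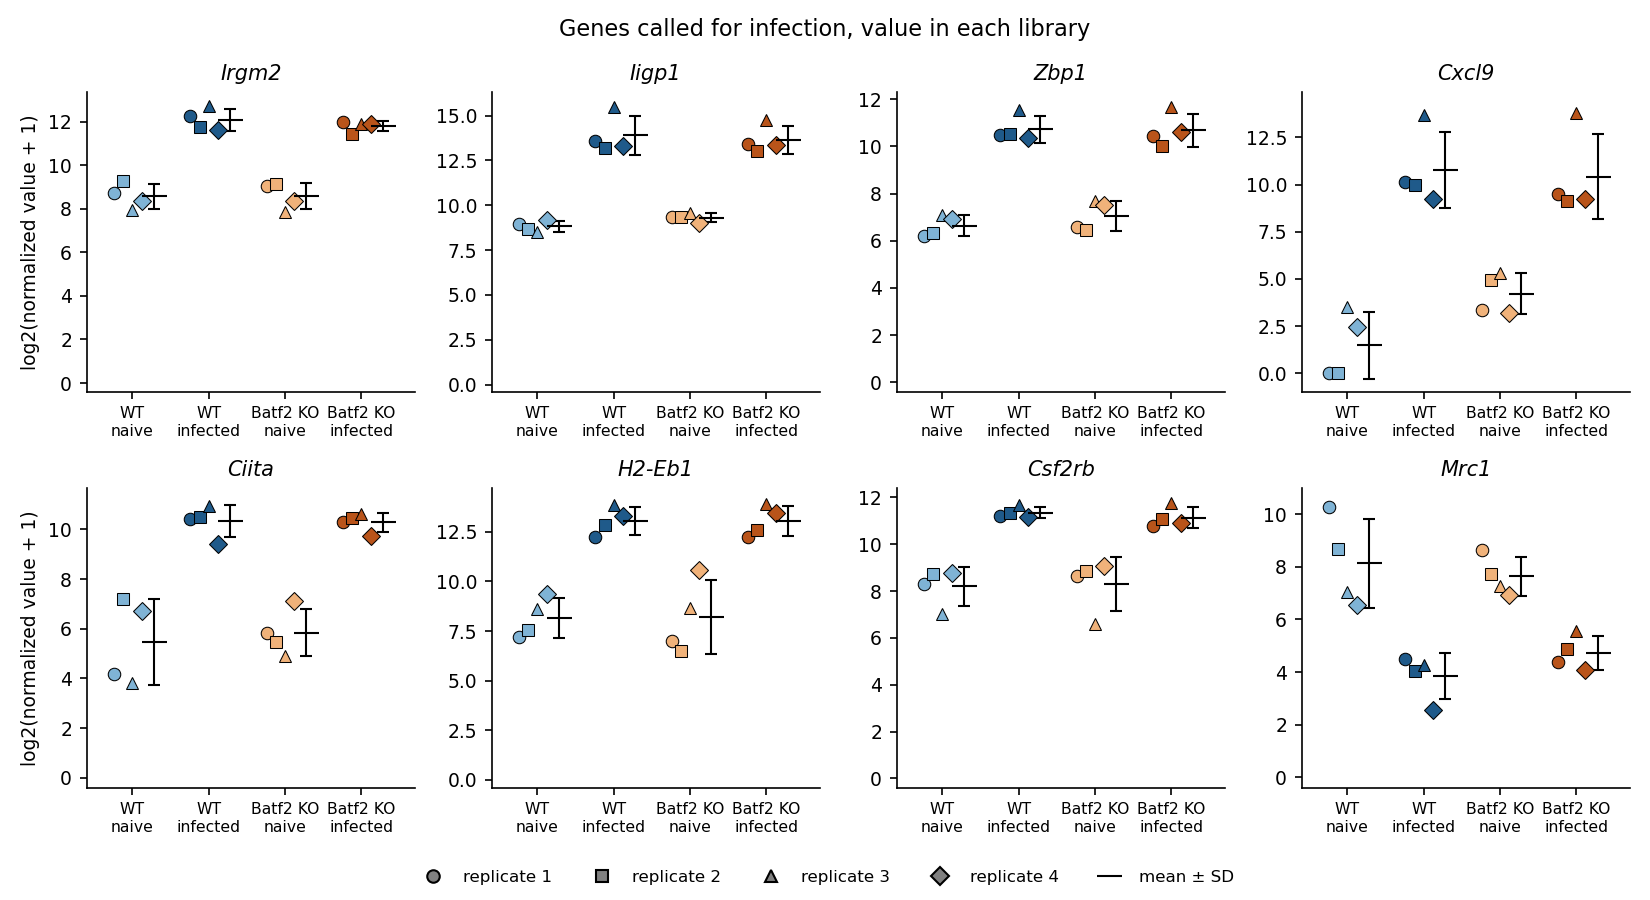
Level of 8 genes called for infection, as log2(normalized value + 1), in each of the 16 libraries, with the group mean ± SD and replicate numbers as shapes. Irgm2 rises from 403 to 4587 normalized counts in WT and from 409 to 3619 in KO, and Mrc1 lies lower in infected than in naive libraries.

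The second comparison asked which transcripts changed with infection in HSCs lacking Batf2. The interferon-gamma GTPases rose here too: 12 of 21 tested members rose, none fell, and the list's median change was 3.55. Iigp1 rose from 641 ± 104 to 14280 ± 9002 (n = 4 each, change 4.32, SE 0.475, limma adjusted p 0.000907). H2-Eb1 rose from 544 ± 686 to 9397 ± 4774 (n = 4 each, change 4.86, SE 0.772). Cd163, a haemoglobin scavenger receptor of macrophages, fell from 187 ± 46.5 to 5.61 ± 4.69 (n = 4 each). In all 36 genes passed, 35 higher and 1 lower, and with the replicate block 211 did, 181 higher and 30 lower, including all 36. Of the 43 genes higher in WT and the 35 higher in KO, 33 were shared, and with the block 160 higher and 25 lower genes were. Chance would give 0.112 for the 33 if genes and genotypes were independent. They are not: same-numbered libraries of different groups correlated at 0.630 to 0.880, and both comparisons share the fit's residual spread.

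The largest increases in KO were those of Apol10b (7.70, SE 0.961), Cxcl11 (6.94, SE 1.33), Serping1 (6.60, SE 0.998), an inhibitor of the complement cascade, Apol9a (6.42, SE 1.10) and Cxcl9 (6.20, SE 1.20). Their naive means were 21.6 for Cxcl9 and 6.92 or less for the others, and Cxcl11 was listed at 0 in all 4 naive KO libraries, so these differences depend on the pseudocount. Small p-values were also found for Irgm2 (3.22, SE 0.369), Zbp1 (3.63, SE 0.434) and Apol7e (3.18, SE 0.397), with limma adjusted p-values of 0.00114, 0.00151 and 0.00183. The only called decrease was that of Cd163 (change -5.28, SE 0.996, limma adjusted p 0.0386), a call lost in all 8 fits that left out 1 KO library (adjusted p 0.0568 to 0.148). For Cd163 the authors' deposited DESeq2 table gave -0.95 (SE 0.322, adjusted p 0.0919) in KO, with a mean level of 1019 against 125 in the gene table. Each called gene named here moved in 1 direction in 4 of 4 same-numbered pairs. Serping1 lies on chromosome 2 (84765387 to 84775444, minus strand) and Cd163 on chromosome 6 (124304656 to 124330527, plus strand).

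Immune lists rose in KO as well. The GTPases gave a camera adjusted p of 6.81e-78 in limma, and 0.000219 with an estimated correlation, and 19 of 21 members passed adjusted over the list alone. Of 39 antiviral genes 5 rose, among them Zbp1 and Oasl2 (1.84, SE 0.283), and 13 passed adjusted over the list alone (median 1.46, camera adjusted p 7.37e-39, and 0.000219 with an estimated correlation). With the block 36 had an unadjusted p under 0.05 in limma, against 18 without it. Counts of risen members in this paragraph are without the block unless it is named. Of 21 interferon signalling genes 9 passed adjusted over the list alone (median 1.02, adjusted p 3.63e-18, and 0.00391 with an estimated correlation), while Irf8 changed by 1.85 and did not pass (limma adjusted p 0.910, and 0.0179 with the block). Of 20 class I genes 0 passed over all genes in limma (6 at an unadjusted p under 0.05), 3 adjusted over the list alone and 17 with the block, and the list rose (median 1.032, adjusted p 1.81e-13, and 0.0160 with an estimated correlation). H2-D1 and B2m changed by 0.64 and 0.77. Of 12 class II genes 2 rose, H2-Eb1 and Ciita (4.45, SE 0.713), and 5 passed adjusted over the list alone (median 2.79, adjusted p 2.04e-18, and 0.0161 with an estimated correlation). Of 18 chemokine, cytokine and checkpoint genes 2 rose, Cxcl9 and Cxcl11, and 7 passed adjusted over the list alone (median 2.43, and 2.26 without Cxcl11 and Nos2, each at 0 in a whole group; adjusted p 5.80e-20, and 0.00616 with an estimated correlation). Of 20 cell death genes 2 rose, Apol9a and Casp12 (1.89, SE 0.304), and 4 passed adjusted over the list alone (median 0.61, adjusted p 3.10e-09, and 0.00616 with an estimated correlation).

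Other lists differed in how far their calls held in KO. NF-kB and TNF targets had a median of 1.30 (21 tested, adjusted p 3.82e-09), lost at adjusted p = 0.0761 with an estimated correlation; 0 members passed over all genes in limma or adjusted over the list alone, and 4 had an unadjusted p under 0.05. Of 20 macrophage and monocyte markers 1 fell, Cd163, 8 fell adjusted over the list alone and 11 with the block (median -2.17, adjusted p 1.96e-20, and 0.00616 with an estimated correlation). Mrc1 was 221 ± 126 in naive and 27.7 ± 13.5 in infected KO cells (n = 4 each, limma adjusted p 0.302, and 0.0121 with the block). Medians were -1.10 for erythroid markers (15 tested, adjusted p 0.000173), 0.61 for dendritic markers (9 tested, 0.0350), -0.27 for S phase genes (30 tested, 0.000173), -0.21 for G2 and mitosis genes (30 tested, 0.0292), -0.24 for ribosomal proteins (43 tested, 0.000132) and -0.29 for oxidative phosphorylation (50 tested, 0.000360). These 6 calls were lost at adjusted p = 0.204, 0.1495, 0.204, 0.302, 0.569 and 0.774 with an estimated correlation. With 1 KO library left out, the list calls in KO held in all 8 fits, except those of ribosomal proteins (6 of 8), S phase genes (7), G2 and mitosis genes (4), oxidative phosphorylation (5), dendritic (4) and erythroid markers (7). Without KO naive library 3 the oxidative phosphorylation median was 0.26 (adjusted p 0.140), and without KO infected library 4 the erythroid median was -0.44 (adjusted p 0.0905). Of the macrophage markers 11, and of the dendritic markers 1, had an unadjusted p under 0.05; in the other 5 lists none did.

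The remaining lists did not pass in KO. Medians were 0.26 for HSC self-renewal (37 tested, adjusted p 0.116, and 0.0368 with the block), 0.08 for myeloid commitment (33 tested, 0.197), 0.22 for lymphoid priming (20 tested, 0.0917, and 0.0195 with the block) and -0.19 for megakaryocyte and erythroid priming (29 tested, 0.3002, and 0.0213 with the block). The 3 calls made with the block were lost at adjusted p = 0.521, 0.265 and 0.129 with the block and an estimated correlation. In these 4 lists, Csf2rb rose (2.83, SE 0.520, limma adjusted p 0.0332), from 376 ± 196 to 2326 ± 809, and 0 other members passed in limma without the block, over all genes or adjusted over the list alone. Besides it, 1 HSC gene and 1 megakaryocyte or erythroid gene had an unadjusted p under 0.05. With the block there were 6 HSC, 5 myeloid, 6 lymphoid and 8 megakaryocyte or erythroid genes. Immediate-early genes (25 tested, median 0.30) and neutrophil markers (16 tested, -0.13) both gave an adjusted p of 0.207. The p53 targets had a median of 0.03 (24 tested, adjusted p 0.895) and the test's direction was down. B and plasma cell markers had a median of 0.09 (13 tested, adjusted p 0.3002), a mean of -0.37 and a test direction of down. T and NK markers had a median of -0.01 (10 tested, adjusted p 0.848) and a mean of 0.19, stromal markers a median of -0.06 (13 tested, adjusted p 0.939) with the test upward, and basophil markers a median of 0.56 (8 tested, adjusted p 0.514). The T and NK list passed in WT and not in KO, and the difference between the responses was -1.25 (adjusted p 0.00993, lost at adjusted p = 0.231 with an estimated correlation).

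The KO count of 36 was lower in each fit that left out 1 of the 8 KO libraries, from 14 without KO infected library 3 to 24 without KO naive library 3. It was 9 with only the KO groups in the fit, 42 in libraries 1 and 2 only, and 0 in libraries 3 and 4 only. There limma gave 526 genes at an unadjusted p under 0.05 without the block, fewer than the 669 given by chance, and 801 with it. The median log2 level of the GTPase list was 8.41 and 8.20 in KO naive libraries 3 and 4. It was 13.7 and 11.9 in the infected ones. Over all libraries 394 genes had an unadjusted p under 0.05, and 1607 with the block. Calls held in all 8 leave-out fits for Iigp1, Irgm2, Zbp1, Apol7e and Apol10b, in 7 for Oasl2 and Serping1, in 6 for H2-Eb1, in 4 for Casp12, in 3 for Ciita, in 2 for Apol9a and Csf2rb, and in 0 for Cxcl11 and Cxcl9. Non-overlapping values were seen in 299 genes (2.23%). The 2.86% given by chance holds only for exchangeable libraries, and KO against WT gave 0.262% in naive and 0.359% in infected cells. Equal column totals moved the median of all genes to 0.116.

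**Figure D4:**
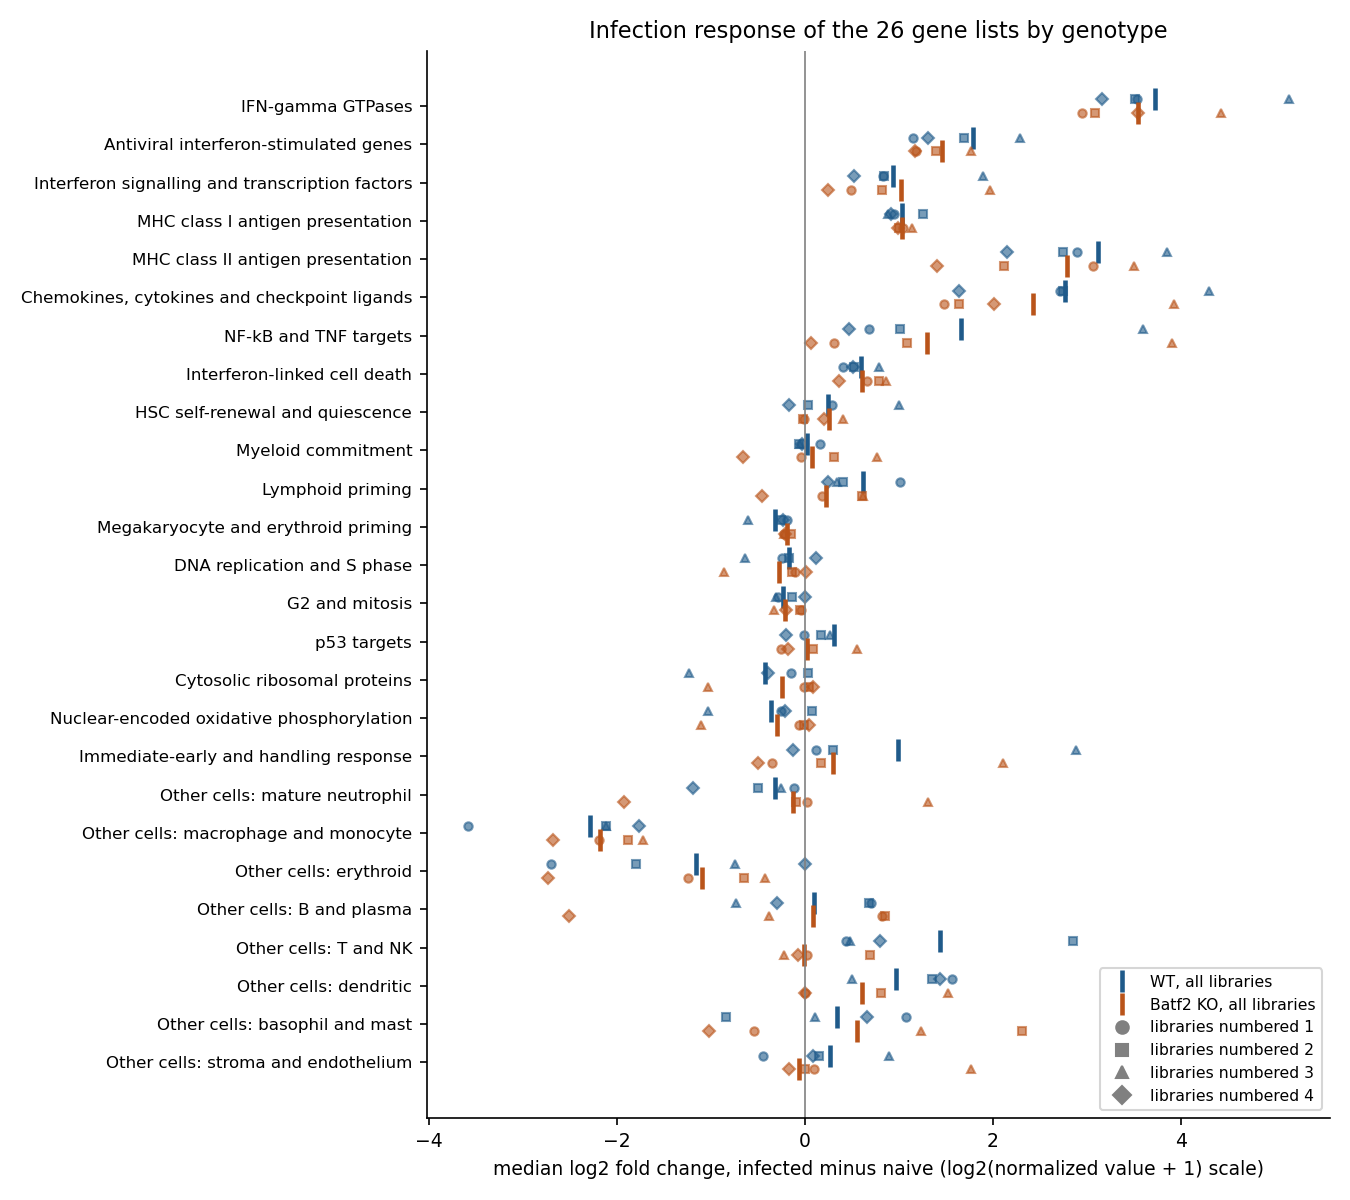
Median log2 change after infection of each of the 26 gene lists in WT and in KO, with a point per same-numbered pair of libraries. The interferon-gamma GTPases stand at 3.72 in WT and 3.55 in KO, and macrophage and monocyte markers at -2.28 and -2.17.

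The third comparison asked what loss of Batf2 changed in naive HSCs. No gene passed in limma: 0 of 13384 over all genes with or without the replicate block, with 92 at an unadjusted p under 0.05 (341 with the block), where 669 are given by chance. Counts so far below chance leave open that these p-values are too large, so 0 calls do not show that nothing changed. In libraries 1 and 2 only the unadjusted count was 717 (951 with the block), and in libraries 3 and 4 only 95 (119 with the block). Batf2 itself was 48.8 ± 39.6 in WT (n = 4) and listed at 0 in KO (n = 4), a difference of -4.96 (SE 0.904, limma adjusted p 0.896) that depends on the pseudocount, with an exact permutation p of 0.0286, the smallest possible. It passed only without WT naive library 2 among the leave-out fits (-5.85, adjusted p 0.0404). Iigp1 was 457 ± 97.3 in WT and 641 ± 104 in KO (n = 4 each) and did not pass.

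Among lists in naive cells, 7 passed camera at the preset correlation and none with an estimated correlation. Medians were 0.17 for the GTPases (adjusted p 0.00539), 0.24 for antiviral genes (0.00886), 0.54 for chemokine genes (0.00886), 0.20 for lymphoid priming (0.00829), 0.31 for immediate-early genes (0.00473), 0.90 for T and NK markers (0.00829) and -0.34 for macrophage markers (0.00886). In the same order the calls were lost at adjusted p = 0.658, 0.658, 0.658, 0.186, 0.686, 0.157 and 0.658 with an estimated correlation. In these 7 lists 0 members passed in limma without the block, over all genes or adjusted over the list alone, and 2 chemokine genes had an unadjusted p under 0.05. With the block 2 GTPases, 4 antiviral genes, 4 chemokine genes and 2 T and NK markers did. Still in that order, the calls held in 3, 3, 2, 5, 4, 5 and 4 of the 8 fits that left out 1 library. The antiviral median ranged from 0.069 to 0.34 (adjusted p up to 0.352) and the chemokine median from -0.027 to 0.71 (up to 0.306), and the GTPase median lay below the 0.28 to 0.37 of these fits. Without WT naive library 3 the immediate-early median was -0.25 (adjusted p 0.0555), and in libraries 3 and 4 only the macrophage median was 0.16 (adjusted p 0.381). The other 19 lists had medians from -0.19 for erythroid to 0.29 for stromal markers, with adjusted p-values of 0.0647 and above. With the block 3 of these passed, megakaryocyte and erythroid priming (-0.094, adjusted p 0.0437), G2 and mitosis genes (-0.072, 0.0249) and B and plasma cell markers (0.22, 0.0295), and were lost at adjusted p = 0.566, 0.754 and 0.754 with the block and an estimated correlation.

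The fourth comparison asked what loss of Batf2 changed in infected HSCs. Batf2 was 1308 ± 1681 in WT and listed at 0 in KO (n = 4 each, difference -9.60, SE 0.904, limma adjusted p 0.000184, exact permutation p 0.0286). The size of that difference is set by the pseudocount, and was -6.30 with a pseudocount of 10. Interferon targets did not pass: Iigp1 was 19400 ± 17720 in WT and 14280 ± 9002 in KO, and Irgm2 4587 ± 1663 and 3619 ± 567 (n = 4 each). The only other gene to pass was Gm4724, a predicted protein-coding gene on chromosome 2 (175422300 to 175435807, minus strand), at 133 ± 75.3 in infected KO cells and listed at 0 in the other 12 libraries (6.83, SE 0.645, limma adjusted p 0.000184). This size too is set by the pseudocount, and was 3.64 with a pseudocount of 10. Of the 50-base windows of the annotated Gm4724 transcripts, 99.8% also occur in transcripts of other genes, 61 in number, against 0.111% for Batf2. The authors' DESeq2 table, whose mean for Gm4724 was 9.36 against 33.1 in the gene table, gave its infection change in KO as 0.04 (SE 1.27) with no adjusted p. That table holds no comparison of KO with WT.

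With the replicate block 1 further gene passed in infected cells, Rpph1, the RNA of ribonuclease P (-3.00, block SE 0.436, limma adjusted p 0.0302), on chromosome 14 (50807449 to 50807767, minus strand). Its mean was 49070 in the gene table and 25.5 in the authors' DESeq2 tables, and 68.1% of its 50-base windows also occur in transcripts of 1 other gene. Limma gave 19 genes at an unadjusted p under 0.05, and 61 with the block, where 669 are given by chance. As in naive cells, so low a count leaves open that the p-values are too large. With infected libraries 1 and 2 only, or 3 and 4 only, 0 genes passed (75 and 58 unadjusted), and Batf2 differed by -8.63 (adjusted p 0.294) and -10.58 (adjusted p 0.108). Of the 26 lists 1 passed, and 1 to 18 did with 1 library left out (18 without KO infected library 3). This was ribosomal proteins (43 tested, median 0.19, adjusted p 5.07e-08), lost at adjusted p = 0.991 with an estimated correlation. With the block 4 passed, the GTPases (-0.14, adjusted p 0.0263), HSC self-renewal (0.076, 0.0483) and S phase genes (-0.074, 0.00118) besides the ribosomal proteins, and these 3 were lost at adjusted p = 0.859 with the block and an estimated correlation. Without the block or WT infected library 3 the GTPases passed in the other direction (0.34, adjusted p 0.00287). The ribosomal median was 0.0056 without WT infected library 3 (adjusted p 0.708) and -0.0053 without WT infected library 4 (adjusted p 0.444). The other 25 medians lay between -0.16 for T and NK markers and 0.34 for basophil markers, and 0 list members passed in limma or had an unadjusted p under 0.05.

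The fifth comparison asked whether the infection response itself differed between genotypes. Gm4724 was the only gene to pass (6.83, SE 0.911, limma adjusted p 0.0283), and its call was lost with the block (adjusted p 0.198) and in 15 of 16 fits leaving out 1 library, all but that without KO infected library 3. In the authors' tables the infection change of Gm4724 was -0.11 in WT (SE 1.28) and 0.04 in KO (SE 1.27). With the block 0 genes passed in limma, and 38 genes without it and 142 with it had an unadjusted p under 0.05. Chance gives 669, so these p-values too may be too large. For Batf2 the difference was -4.64 and did not pass (limma adjusted p 1). Iigp1 rose by 5.07 in WT and 4.32 in KO, and Irgm2 by 3.52 and 3.22.

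Of the 26 lists 8 passed for this difference at the preset correlation and none with an estimated correlation. Medians were -0.31 for the GTPases (adjusted p 0.000136), -0.31 for antiviral genes (0.00156), -0.44 for chemokine genes (0.00866), -0.19 for lymphoid priming (0.0124), -0.46 for immediate-early genes (0.000143), -1.25 for T and NK markers (0.00993), -0.30 for dendritic markers (0.0171) and 0.17 for ribosomal proteins (0.00349). In the same order the calls were lost at adjusted p = 0.554, 0.493, 0.623, 0.232, 0.623, 0.231, 0.232 and 0.943 with an estimated correlation. Still in that order, the calls held in 15, 12, 7, 9, 15, 11, 7 and 9 of the 16 fits that left out 1 library. Without WT infected library 3 the GTPase median was -0.08 (adjusted p 0.770) and the antiviral median -0.13 (adjusted p 0.543), and without KO infected library 3 they were -0.70 (adjusted p 2.31e-11) and -0.40 (adjusted p 1.19e-05). Without WT naive library 3 the immediate-early median was 0.24 (adjusted p 0.393), and without KO naive library 4 the ribosomal median was -0.093 (adjusted p 0.635). The other 18 medians lay between -0.36 for basophil and 0.23 for macrophage markers, with adjusted p-values of 0.301 and above; class II (-0.25) passed with the block (adjusted p 0.0435), lost at adjusted p = 0.770 with the block and an estimated correlation. In all 26 lists 0 list members passed in limma or had an unadjusted p under 0.05.

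Over the 135 genes that passed for infection averaged over genotypes, the median response was 2.83 in WT and 2.58 in KO, and Pearson's r between the responses was 0.942 across genes, which are not independent replicates. The median difference was -0.34 (two-sided permutation p 0.358 over 4900 relabellings). Over 80 interferon and class I list genes it was -0.22 (permutation p 0.583). It was 0.0044 without WT infected library 3, -0.41 without KO infected library 3, -0.15 without both (permutation p 0.479) and -0.16 without number 3 in all groups (permutation p 0.440). Permuting within same-numbered pairs gave -0.09 over 851 genes (permutation p 0.219 over 256 relabellings) and -0.22 over the 80 list genes (permutation p 0.0156, where 0.00781 is the smallest possible). Permuting within libraries 1 and 2 and within libraries 3 and 4, without pairs, gave a permutation p of 0.350 for the same -0.22 (1296 relabellings). By number the 80-gene difference was -0.010, -0.236, -0.350 and 0.028, and within libraries 1 and 2 it was -0.14 (permutation p 0.444) and within libraries 3 and 4 -0.19 (permutation p 0.556).

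**Figure D5:**
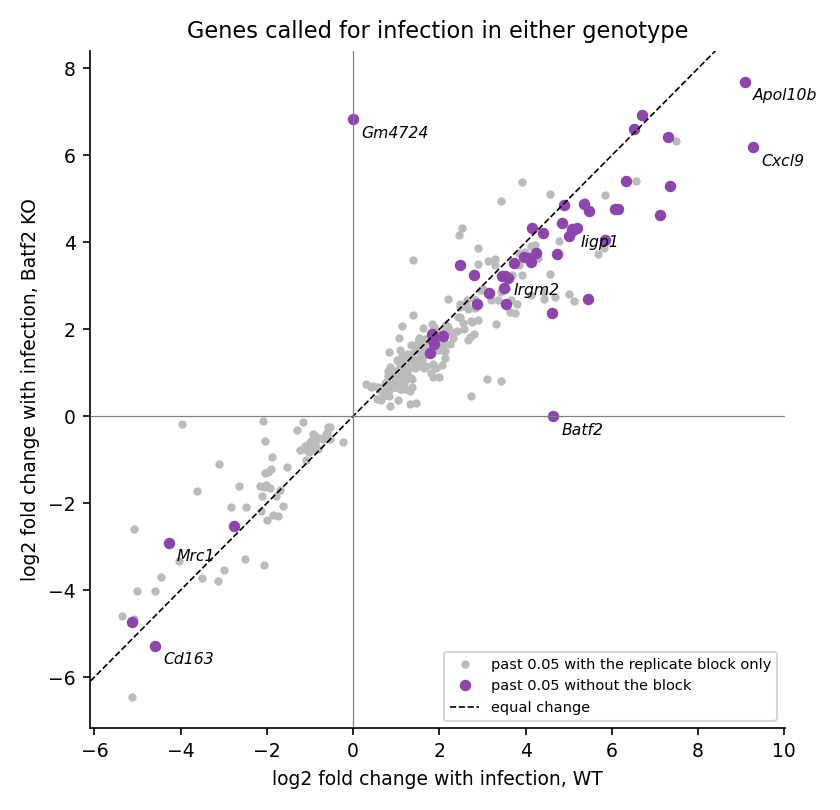
Log2 change after infection in KO against that in WT for each gene called in either genotype, with genes called only with the replicate block in grey and the line of equal response. Iigp1 lies at 5.07 in WT and 4.32 in KO, and Gm4724, 99.8% of whose 50-base transcript windows occur in other genes, at 0 in WT and 6.83 in KO.

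The authors' deposited DESeq2 tables listed 620 genes past an adjusted p of 0.05 for infection in WT (446 higher, 174 lower) and 423 in KO (318 higher, 105 lower), with 257 higher and 65 lower genes shared. Of the limma calls without the block, 39 of 39 listed in the WT table and 28 of 30 in the KO table passed there in the same direction; the 2 exceptions were Gm4724 and Cd163. With the block these counts were 259 of 278 and 165 of 183. Across tested genes with a mean above 100, Pearson's r between limma and deposited log2 changes was 0.922 in WT (9701 genes) and 0.905 in KO (9744 genes), and 81 and 70 genes differed by more than 1. Batf2 changed by 4.54 in the deposited WT table (SE 0.815, adjusted p 2.98e-06) and by 0.50 in the KO table (SE 0.851, adjusted p 0.824), with a mean level of 1061 against 339 in the gene table. Those tables give no level per group, so whether Batf2 was also at 0 in KO in that quantification is not known. In the deposited enrichment tables the Hallmark interferon-gamma response led by adjusted p in both genotypes (163 genes, CERNO adjusted p 1.44e-65 in WT and 1.91e-64 in KO), with an area under the curve of 0.809 in each. By area the Hallmark interferon-alpha response stood higher, at 0.880 in WT and 0.885 in KO (81 genes). For KO against WT 6 sets were listed in naive cells and 1 in infected cells, and 1 for the difference in response.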

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

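Of the tests in this part, those of naive library 3 against naive library 4 and of the sex of the animals were chosen after the result was seen, and so was the comparison with the authors' tables. Of 98 group values tested, 15 had 1 library far from the other 3, where chance gives about 1 in 20. The number given for each is the gap to the nearest library divided by the range of the group. In infected WT library 3 it was 0.904 for Apol9b (1248 against 286 to 330), 0.873 for Zbp1 (2994 against 1306 to 1452), 0.871 for Casp12 (1927 against 1094 to 1177) and 0.845 for Cxcl11 (1982 against 33.2 to 63.1). In infected KO library 3 it was 0.911 for Cxcl9 (13967 against 550 to 734) and 0.975 for Cxcl11 (2284 against 43.4 to 48.0). In infected KO library 2 it was 0.843 for Irgm2 (2782 against 3811 to 4042), and in infected WT library 1 it was 0.922 for Cd163 (0 against 16.4 to 21.2). The share of the 100 highest genes gave 0.882 in naive WT library 2 (19.5% against 18.4% to 18.5%).

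The other 6 had a value above 0 in 1 library and 0 in the other 3, which gives a ratio of 1 whatever the value. These were Apol10b in naive WT library 4 (4.66), Apol9a in naive WT library 3 (5.76) and naive KO library 3 (27.7), Cxcl11 in naive WT library 3 (1.16), Serping1 in naive KO library 4 (11.5) and Siglec1 in infected KO library 2 (2.63).

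Gm4724 was singled out because its infection response differed between genotypes in the test of the difference (6.83), being listed at 0 in 12 libraries and at 44.4 to 210 in the infected KO libraries. The 6.83 depends on the pseudocount. The authors' DESeq2 tables gave an infection change of 0.04 (SE 1.27) in KO, and 99.8% of the 50-base windows of its transcripts occur in other genes. How the authors divided shared reads between these genes is not stated, and no biological explanation of this value was tested.

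The pairs numbered 3 also stood apart in whole lists: the median infection change of immediate-early genes was 2.89 in the WT pair and 2.11 in the KO pair with that number. A difference in sex between naive and infected libraries is not needed for the shift: the KO pair numbered 3, with little or no Y-linked RNA in either library (Ddx3y 2.57 in naive and 0 in infected, against 362 to 1213 in 13 other libraries), showed that 2.11. In the WT pair Ddx3y was 368 in naive and 0 in infected library 3, so sex and infection cannot be told apart there. Xist, an RNA of female cells, was 580 in that naive library. In libraries 1 and 2 of all groups Xist was 13954 to 31148 beside Ddx3y of 535 to 1213. Libraries may thus hold RNA of both sexes, and Ddx3y above 0 does not mark a library as male. Whether sex sets number 3 apart from the other numbers was not tested. For this list the shift may lie in the naive libraries: immediate-early genes were lower in naive library 3 than in naive library 4 by a median of -2.91 in WT and -1.92 in KO, while the infected libraries differed by 0.20 and 0.68. For the interferon-gamma GTPases it was the infected library 3 that stood above library 4, by 2.06 in WT and 1.59 in KO, against -0.14 and 0.60 in naive libraries. Kit, used for enrichment, was also lower in libraries 3: 1859 and 1303 in naive and 3712 and 2580 in infected WT and KO. In all other libraries Kit was 6065 to 11510. Neutrophil markers differed, library 3 minus library 4, by a median of -2.77 and -2.38 in naive and -1.34 and 1.04 in infected WT and KO. Whether the mix of sorted cells differed was not tested. Handling of those samples, and a difference between the animals, stay open as well, and the labels name neither.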

How the results depend on the processing

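Alternatives chosen after the data were seen were pseudocount 10, equal column totals, quantile normalization, the first residual component, libraries 1 and 2 only, libraries 3 and 4 only, each combination with the replicate block other than the block itself, leaving out infected library 3 of both genotypes or number 3 in all groups, and the set (1 and 2, or 3 and 4) as a block. Not run were RLE factors, DESeq2, voom and svaseq, which need raw counts, and a batch named in the labels, of which there was none. A direction counts as turned only where the result passed the threshold before or after, so sign changes of results that never passed count as unchanged. Of the values of single genes under the alternatives, 5549 kept direction and side of the threshold, 187 lost the call, 15 gained it and 0 turned; of the values of lists, 2410 kept both, 207 lost the call, 165 gained it and 26 turned. Reads estimated ranged from 5940000 to 17700000 per library, and the values give no whole reads, so no counting error could be set beside a level of 0. In simulated data with 50 genes shifted by each fold, over the 4 comparisons of 2 groups, the unblocked fit recovered 0% at 2-fold, 32% (infection in KO) to 58% at 8-fold and 48% (infection in WT) to 78% at 16-fold. The fit with the block, on whose model the data were built, recovered 34% to 46%, 78% to 98% and 86% to 98%. Real recovery may be lower. Except where a value shows otherwise, the cause was not tested.

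With an estimated correlation the number of lists that passed was 11 for infection in WT, 8 in KO, and 0 for KO against WT in naive cells, in infected cells and for the difference in response; with the block as well it was 10, 8, 0, 0 and 0 (in WT NF-kB and TNF targets and lymphoid priming were lost and megakaryocyte and erythroid priming gained). With no filter on low values Batf2 in WT changed by 4.64 (adjusted p 0.0560, more genes being tested), 4 lists passed in naive cells, 4 genes in infected cells and 5 lists for the difference. With a stricter filter 0 genes and 6 lists passed in infected cells, and 0 genes and 5 lists for the difference; Batf2 and Gm4724 fall outside that filter. With only the compared groups, and so fewer libraries, 18 genes passed in WT, 9 in KO, and Batf2 in WT (4.64) had an adjusted p of 0.354.

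With the replicate block 316 genes passed in WT, 211 in KO and 0 for the difference, 4 lists passed in infected cells, and the median difference over the interferon and class I lists (-0.22) had a permutation p of 0.0156. The block lowered the median SE from 0.661 to 0.274. With the set as a block 229 genes passed in WT, 143 in KO, 0 in naive cells, 3 in infected cells and 0 for the difference (median SE 0.322), and the permutation p within sets was 0.350. With the first residual component 268 genes passed in WT, 164 in KO, 0 for the difference, and 3 lists in infected cells. With pseudocount 10, 2 lists passed in infected cells; with quantile normalization 2 did, and Batf2 in WT changed by 4.28 (adjusted p 0.0565).

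In libraries 1 and 2 only, 86 genes passed in WT, 0 in infected cells and 0 for the difference, 4 lists passed in infected cells, and Batf2 changed by 5.09 in WT (adjusted p 0.117) and by -8.63 in infected cells (0.294). In libraries 3 and 4 only, 0 genes passed in WT, in KO, in infected cells and for the difference, 2 lists passed in infected cells, and Batf2 changed by 4.20 in WT (adjusted p 0.430) and by -10.58 in infected cells (0.108). There the macrophage median was 0.16 for KO against WT in naive cells and -0.37 for the difference, and the erythroid median for the difference was -0.68. Added to the block, libraries 1 and 2 only gave 117 genes in WT, 65 in KO and 0 in infected cells, and libraries 3 and 4 only gave 0, 0 and 0. Also with the block, equal column totals gave 1 gene in naive cells, quantile normalization 1 and no filter 1 for the difference, and the stricter filter 0 in infected cells.

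Leaving out 1 library at a time gave 32 to 49 genes for infection in WT, 14 to 24 in KO (14 without KO infected library 3), 0 to 1 in naive cells (1 without WT naive library 2), 2 to 2 in infected cells and 0 to 1 for the difference (1 only without KO infected library 3). Batf2 ranged from 3.75 to 5.12 in WT, from -5.85 to -4.48 in naive cells, from -10.00 to -8.84 in infected cells and from -5.12 to -3.75 for the difference. Lists that passed numbered 15 to 21 in WT, 11 to 17 in KO, 1 to 14 in naive cells, 1 to 18 in infected cells (18 without KO infected library 3) and 4 to 12 for the difference. The median difference ranged from -0.54 to -0.08, and over the interferon and class I lists from -0.41 to 0.0044. Leaving out 1 number at a time with the block gave 156 to 315 genes in WT, 111 to 212 in KO, 0 to 1 in naive cells, 1 to 3 in infected cells and 0 to 0 for the difference.

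Lists turned direction with 1 library left out, and their medians ranged as follows. These fits had no block, so part of a turn can come from sets left unbalanced between the groups compared. For infection in KO, oxidative phosphorylation ranged from -0.63 to 0.26 (turned without KO naive library 3). For KO against WT in naive cells the ranges were -0.54 to 0.45 for oxidative phosphorylation (turned without WT naive 3, KO naive 1 and KO naive 2), -0.25 to 0.91 for immediate-early genes (WT naive 3), -0.38 to 0.22 for myeloid commitment (WT naive 4), -0.19 to 0.27 for ribosomal proteins (WT naive 4 and KO naive 3) and -0.87 to 0.68 for neutrophil markers (KO naive 4). For KO against WT in infected cells the ranges were -0.55 to 0.34 for the GTPases, -0.65 to 0.41 for chemokine genes and -0.40 to 0.41 for NF-kB and TNF targets, each turned without WT infected library 3. They were -0.29 to 0.37 for myeloid commitment, -0.21 to 0.36 for oxidative phosphorylation, -0.34 to 0.78 for neutrophil and -0.49 to 0.71 for erythroid markers, each turned without KO infected library 3. For the difference in response the ranges were -0.43 to 0.64 for oxidative phosphorylation (turned without WT naive 3, KO naive 1 and KO naive 2), -0.84 to 0.24 for immediate-early genes (WT naive 3), -0.53 to 0.96 for neutrophil markers (WT naive 4 and KO naive 1) and -0.093 to 0.38 for ribosomal proteins (KO naive 4).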

Other observations

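Outside the gene lists, 75 genes higher and 13 lower after infection passed with the replicate block in both genotypes; those named in this paragraph were chosen after their values were seen. Ly6a, which encodes the stem cell surface antigen Sca-1 used in sorting, rose by 3.42 in WT and 2.85 in KO (block SE 0.254 for each, limma adjusted p 2.13e-06 and 1.59e-05), in 4 of 4 pairs of each genotype. The serine protease inhibitors Serpina3f (6.34 and 5.398, block SE 0.519) and Serpina3g (2.66 and 2.46, block SE 0.343), the complement genes C1ra (1.87 and 1.66) and C4b (6.15 and 4.78), and the integrin subunit Itgb7 (2.14 and 2.07) rose in both. So did Csf2rb2, a cytokine receptor chain (4.15 and 4.33), Il12rb1, a chain of the interleukin 12 receptor (2.80 and 3.25), and Ifitm3, an antiviral membrane protein (1.21 and 1.02). Trib2, a pseudokinase (-2.06 and -1.64), Rgs10, a regulator of G protein signalling (-1.90 and -1.22), and Fcna, a ficolin of macrophages (-5.12 and -6.46), fell in both. Among list members, Car1, a carbonic anhydrase of red cells (-2.13 and -2.19), and Hmox1, a haem-degrading enzyme (-3.50 and -3.73), fell in both genotypes with the block. Without the block Csf2rb2, C4b and Il12rb1 passed in KO.

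Within 2000000 bases on each side of Batf2, 125 genes were tested and 0 passed in limma for KO against WT in either condition, with or without the block; with the block 1 in naive and 2 in infected cells had an unadjusted p under 0.05. Rpph1, chosen after its values were seen, was 101570 to 225280 in WT libraries 1 and 2 and 6537 to 15990 in the KO libraries with those numbers, and 0 to 14.8 in libraries 3 and 4. Rmrp, a related RNA, was 3708 to 10616 in all 8 libraries numbered 1 and 2 and 0 in all 8 numbered 3 and 4.

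The test of depth and the 3 tests of a smaller response in KO were chosen after the result was seen; those of histone genes, transcript length and other splits were not, except that of genes shared by both genotypes. Libraries 1 and 2 differed from libraries 3 and 4 in every group, with 3820 genes higher by more than 1 on the log2 scale in the first set and 3876 in the second. Depth alone was argued against: among the 1000 highest genes the median absolute difference was 1.25. A difference in RNA selection during library preparation is a candidate explanation, since 67 histone genes, whose transcripts lack a poly(A) tail, were higher in libraries 1 and 2 by a median of 5.65 or more in every group. Transcript length also followed the difference (Spearman rho 0.615 across genes), longer transcripts being higher in libraries 1 and 2. A length effect in that direction would not by itself raise short RNAs in those libraries. The lengths of the histone genes were not compared with it. RNA selection and a length effect can also hold together, so both explanations stay open. The labels name 1 protocol for all samples.

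A weaker infection response without Batf2 is a hypothesis of this re-analysis, from the median difference of -0.22 over the interferon and class I lists. Whether it rests on infected WT library 3 was not decided: the difference was 0.0044 without that library and -0.41 without KO infected library 3, so leaving out either moved it, and without both, a fit added after the result was seen, it was -0.15. Leaving out only 1 of them also left the sets unbalanced between the genotypes, which can move the difference by itself. A higher naive level in KO could account for much of it: 70.7% of the mean difference lay in the naive libraries (KO minus WT 0.22 in naive and -0.09 in infected cells). Paired by number, the KO response was the smaller in 3 of 4, which does not decide whether the numbers differ by chance. The permutation p for the -0.22 was 0.583 without pairing and 0.0156 when labels were permuted within same-numbered pairs, and 0.350 when permuted within libraries 1 and 2 and within libraries 3 and 4, so the call depended on reading the numbers as pairs. A lower response in KO was neither shown nor excluded.

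Other ways of splitting the same libraries were run through the same fit. For infection in WT, 2 of 35 splits gave at least the real 46 genes, and in KO 2 of 35 gave at least the real 36, the real split included, so these counts alone do not exclude chance. The 1 other split, with 5190 genes in WT and 6383 in KO, was in each case that of libraries 1 and 2 against 3 and 4, which points to a structure of the samples; with the block the counts were 316 and 211. For the 33 genes called in both genotypes, 2 of 1225 pairs of a WT split with a KO split shared as many in 1 direction. These were the real pair and that of libraries 1 and 2 against 3 and 4 in both (4253 genes), and where neither split was that one the highest other was 0. This does not exclude chance: the pairs treat WT and KO splits as separate, but same-numbered libraries of different groups correlated at 0.630 to 0.880. The test was also chosen after the result was seen. For KO against WT in naive cells the real count was 0, which every one of the 35 splits reaches by definition, so that count says nothing about chance (highest other 7879). In infected cells 2 of 35 gave at least the real 2 (highest other 3165), again the split by number. For the difference in response 7 of 100 relabellings gave at least the real 1 (highest other 5459). Among the 8 splits that part all same-numbered pairs, the highest other gave 0 genes in WT and in KO; with the block the real split was 1 of 8 for each, with a highest other of 0, and 8 splits are too few for a share under 0.05.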
